A study of Homo sapiens with 20 samples.

How the data were processed

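Total RNA of HEY cells was taken 48 hours after transfection, amplified from the 3′ end, labelled with biotin and hybridized to a whole-transcriptome array, per the labels. The miRNA experiment holds 12 arrays (3 each of miR-NC, miR-141, miR-200b and miR-205) and the siRNA experiment 8 (2 each of si-NC, si-ZEB1, si-WNT5A and both siRNAs). The deposited values are log2 signal per probe set, made by the authors with RMA, whose version the labels do not state. Each array has 54675 probe sets, and the median probe set read 3.70 in the miRNA and 4.52 in the siRNA experiment. The value distributions differ between the experiments and are alike within the siRNA arrays, so groups were compared within an experiment. Arrays of both were set together only in an alternative fit of all 20 and in a check of si-NC against miR-NC by percentiles within each array. The labels give 33 nM for precursor miRNA and for siRNA, and state no separate dose for the negative controls or for each siRNA in the double transfection. No further normalization, filter or pseudocount was applied.

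Of all 54675 probe sets 41097 had a single gene symbol, 1801 several and 11777 none in the platform's table. The RefSeq gene table of assembly GRCh38.p14, used only for names, matched 41043 of the 41097 and renamed 0. The 62 probe sets of array controls were left out, 6 of them with a single symbol, which left 41091. Each of 19775 genes was represented by the probe set with the highest mean over all 20 arrays, and 10523 genes had more than 1 probe set. RNA quality was read from the array's control probe sets for the 3′, middle and 5′ parts of GAPDH and ACTB.

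Each experiment was fitted with limma 3.58.1 (R 4.3.3) by lmFit and eBayes with 1 mean per group, giving 8 and 4 residual degrees of freedom, 4.41 and 4.49 prior degrees of freedom, and median residual SDs of 0.38 and 0.105. The comparisons were each miRNA with miR-NC, the miRNAs with one another, each siRNA treatment with si-NC, and the interaction, which is the effect of si-ZEB1 with si-WNT5A present minus its effect without. All tests were 2-sided. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Genes shared by the 3 miRNAs were those called in each with the same sign, set beside independent lists and beside 100 simulated draws of unchanged groups against shared controls.

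Written from general knowledge before the data were examined were 18 gene lists: epithelial, mesenchymal, reported miR-200 family targets, reported miR-205 targets, Wnt pathway, actin and focal adhesion, TGF-beta response, interferon response, mitosis, DNA replication, p53 targets, unfolded protein and ATF4 response, cholesterol synthesis, inflammatory and NF-kappaB targets, small RNA machinery, blood cell markers, endothelial markers and reference genes. Some genes stand in several lists, as ZEB1 and ZEB2 do in the mesenchymal list and both target lists. Each list was tested by limma's camera with a preset correlation of 0.01, adjusted over the 108 tests of the miRNA and the 72 of the siRNA experiment, with camera at an estimated correlation and fry beside it. Of these tests 28 and 19 passed with the preset and 0 and 0 with the estimated correlation. Median, mean and test differed in sign in 23 and 14 tests, none of which passed. Genes called higher or lower in each siRNA comparison were tested as sets in the miRNA comparisons in the same way (18 tests). Matches to the miRNA seeds in 3′ UTRs were not analysed here, as 3′ UTR sequence was not at hand.

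Genes are named by a rule. ZEB1, ZEB2, WNT5A, CDH1, VIM, CDH2 and FN1 are always given. In each comparison with a control the 10 largest rises and 10 largest falls follow, among called genes whose treated arrays all lie beyond all control arrays, and from each list up to 4 genes of smallest p. Between miRNAs and for the interaction the 4 highest and 4 lowest are given, and of the shared genes the 6 rises and 6 falls with the largest smallest change. The comparisons, lists, naming rule and most alternatives were fixed before the data were examined.

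Alternatives were all 20 arrays in 1 fit, only the arrays compared, the replicate number as a fixed effect, the mean of a gene's probe sets, dim genes left out, arrays centred on their medians, quantile normalization again, array weights, an intensity trend with a robust prior, and leaving out each array. Chosen after seeing the data were the GAPDH 3′ minus 5′ difference as a covariate and siRNA sets of at least 2-fold. So was omitting the 3 treated arrays with low 5′ GAPDH signal (which leaves 1 miR-141 array), or miR-141 replicate 3 in comparisons without miR-141. The fits were tested on 19775 simulated genes, 200 of them changed. Far more were called in the data, so recovery there can differ. At 1.5, 2 and 4-fold, 0, 0 and 84.5% were recovered for miR-141 against miR-NC and 35, 87 and 99.5% for si-ZEB1 against si-NC. For the interaction 68.5% were at 2-fold. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.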

Results

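Gene expression was measured on 20 whole-transcriptome arrays of HEY cells, a human ovarian cancer line, taken 48 hours after transfection. In the miRNA experiment the cells had received a negative control precursor (miR-NC) or the precursor of miR-141, miR-200b or miR-205, with 3 arrays in each group. In the siRNA experiment they had received a negative control siRNA (si-NC), siRNA against the transcription factor ZEB1, siRNA against the secreted ligand WNT5A, or both siRNAs, with 2 arrays in each group. miR-141 and miR-200b belong to the miR-200 family and differ in their seed sequence, while miR-205 is unrelated to them in sequence. All 3 miRNAs are known repressors of ZEB1, which holds cells in a mesenchymal state. The study asks whether miRNAs of unlike sequence lead to the same move towards an epithelial state, and how far ZEB1 and WNT5A carry it. Values are log2 signals, changes are treated minus control, and ± is the SE of limma's fit unless SD is named. The p-values measure the spread between these arrays only, since the labels do not say whether replicates were separate cultures. The number of arrays limits the precision.

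The arrays differed in RNA quality. The 3′ control probe sets of GAPDH, a housekeeping transcript, lay above the 5′ ones. The difference was 7.27 ± 0.64 with miR-NC and 1.75 ± 0.39 with miR-205 (SD, n = 3 each). It was 1.99, 6.89 and 7.56 in the miR-141 arrays, 0.65, 1.67 and 5.68 with miR-200b and 0.07 to 0.12 in all 8 siRNA arrays. For ACTB group means ran from 7.33 (miR-205) to 9.51 (miR-NC), and from 0.37 to 0.55 with siRNAs. The median change over all genes was 0.24 with miR-141 (0.095 with arrays centred on their medians), 0.11 with miR-200b and 0.15 with miR-205.

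**Figure D1:**
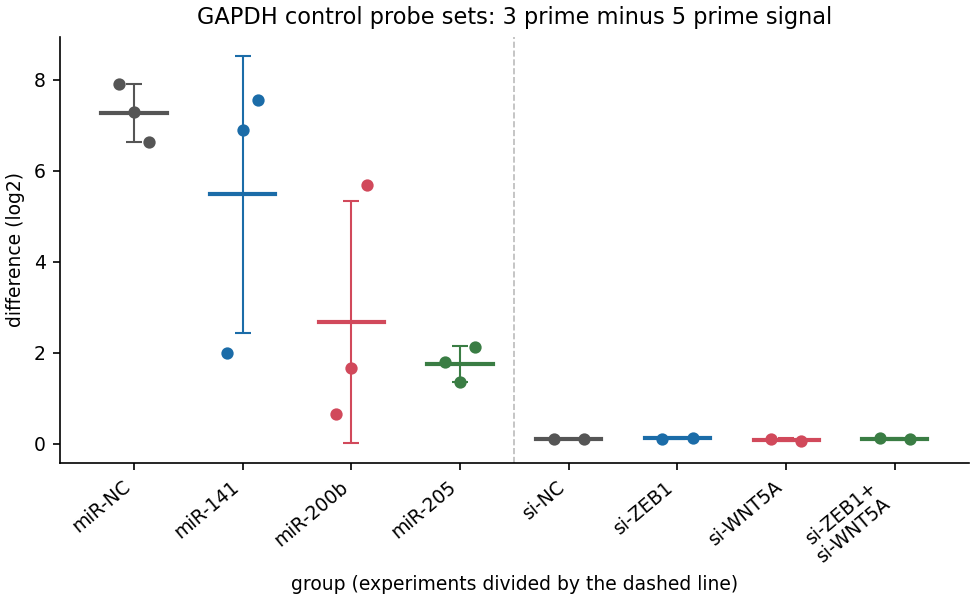
GAPDH 3′ minus 5′ difference (log2, vertical axis) in each of the 20 arrays by group, 1 point an array. The miR-NC arrays lie between 6.63 and 7.90, the miR-205 arrays between 1.34 and 2.11, and the siRNA arrays near 0.

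ZEB1 signal was lower in every array of every miRNA than in every miR-NC array. It averaged 10.46 ± 0.18 (SD, n = 3) with miR-NC, 7.98 ± 2.21 with miR-141, 7.98 ± 0.27 with miR-200b and 9.02 ± 0.35 with miR-205. ZEB1 fell with miR-141 (−2.48 ± 0.76, adjusted p = 0.0329), while the changes with miR-200b (−2.48 ± 0.76, adjusted p = 0.0533) and miR-205 (−1.43 ± 0.76, adjusted p = 0.208) missed the threshold. The SE, pooled over groups, is widened by miR-141 (arrays 9.35, 9.16 and 5.42), whose change without replicate 3 was −1.20. The miR-141 call was lost without miR-NC replicate 1, 2 or 3 (adjusted p = 0.0826, 0.0965 and 0.0687). Of the other 3 ZEB1 probe sets, the brightest fell with each miRNA, by −2.41 with miR-141 (adjusted p = 0.0017), −3.09 with miR-200b (adjusted p = 0.000944) and −2.01 with miR-205 (adjusted p = 0.00452). The next was −0.05 with miR-141 (adjusted p = 0.892) and fell with miR-200b (−1.40, adjusted p = 0.00286) and miR-205 (−0.71, adjusted p = 0.0437). The dimmest fell with miR-141 (−1.62, adjusted p = 0.00888) and miR-205 (−1.25, adjusted p = 0.0327) and missed with miR-200b (−1.05, adjusted p = 0.0947). Without the 3 treated arrays of low 5′ signal (miR-141 replicates 2 and 3 and miR-200b replicate 3), a setting chosen after the data were seen that leaves replicate 1 as the only miR-141 array, ZEB1 passed with miR-200b (−2.43, adjusted p = 0.000113) and miR-205 (−1.43, adjusted p = 0.000423). ZEB2, the paralogue of ZEB1, fell with miR-200b (−1.65 ± 0.25, adjusted p = 0.0022), as did 1 of its 4 other probe sets (−0.91, adjusted p = 0.0343), although the mean of its probe sets did not pass (−0.51, adjusted p = 0.113). It was lower in 3 of 3 arrays of miR-141 (−0.63 ± 0.25, adjusted p = 0.0856) and miR-205 (−0.64 ± 0.25, adjusted p = 0.0905) without passing. Without miR-141 replicate 3 ZEB2 passed with miR-141 (−0.78, adjusted p = 0.0357).

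WNT5A, a ligand of the non-canonical Wnt pathway, was lower in all 9 miRNA arrays than in any miR-NC array. It fell with miR-141 (−1.76 ± 0.47, adjusted p = 0.0179), a call lost without miR-NC replicate 2 (adjusted p = 0.0706). The changes with miR-200b (−1.05 ± 0.47, adjusted p = 0.185) and miR-205 (−1.14 ± 0.47, adjusted p = 0.107) did not pass. The other WNT5A probe set fell with miR-141 (−1.72, adjusted p = 0.000531), miR-200b (−1.79, adjusted p = 0.000957) and miR-205 (−2.03, adjusted p = 0.000194). Without the 3 arrays of low 5′ signal the first WNT5A probe set passed with miR-200b (−0.88, adjusted p = 0.0418) and miR-205 (−1.14, adjusted p = 0.00412) and missed with the 1 miR-141 array left (−1.03, adjusted p = 0.0592).

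FN1, the matrix protein fibronectin and a mesenchymal marker, fell most with miR-200b, from 11.91 ± 0.09 to 8.21 ± 0.83 (SD, n = 3 each; −3.70 ± 0.39, adjusted p = 0.000468). FN1 also fell with miR-141 (−1.35 ± 0.39, adjusted p = 0.0265), a call lost without any miR-NC array or miR-141 replicate 3 (adjusted p between 0.0652 and 0.0744). Its other probe sets passed (−0.97 to −1.80, adjusted p up to 0.0173) or missed (−0.78 and 1.35). FN1 missed with miR-205 (−0.54 ± 0.39, adjusted p = 0.378). So did 5 of its 6 other probe sets (−0.81 to 1.30), while a dim one fell (−1.24, adjusted p = 0.00405). VIM, the intermediate filament vimentin, was lower in 3 of 3 miR-141 arrays without passing (−1.57 ± 0.55, adjusted p = 0.0542), and it passed without miR-141 replicate 1 (−2.26, adjusted p = 0.00408). VIM was not called with miR-200b (−0.41 ± 0.55, adjusted p = 0.714) or miR-205 (−0.20 ± 0.55, adjusted p = 0.842). The other VIM probe set, dimmer at a mean of 4.77 against 12.47, fell with miR-141 (−2.59, adjusted p = 0.00103) and miR-205 (−1.82, adjusted p = 0.00698) and missed with miR-200b (−1.22, adjusted p = 0.0719). With the GAPDH difference as a covariate, a setting chosen after the data were seen, VIM passed with miR-141 (−2.13, adjusted p = 0.00142), miR-200b (−1.86, adjusted p = 0.0261) and miR-205 (−1.94, adjusted p = 0.0298). CDH1, the epithelial cadherin, stayed near background in every group (2.59 with miR-NC, 2.97 with miR-141, 2.75 with miR-200b and 2.82 with miR-205) and was not called. CDH2, the neural cadherin of mesenchymal cells, was not called with any miRNA (0.12, 0.38 and 0.33 with miR-141, miR-200b and miR-205, each ± 0.20).

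**Figure D2:**
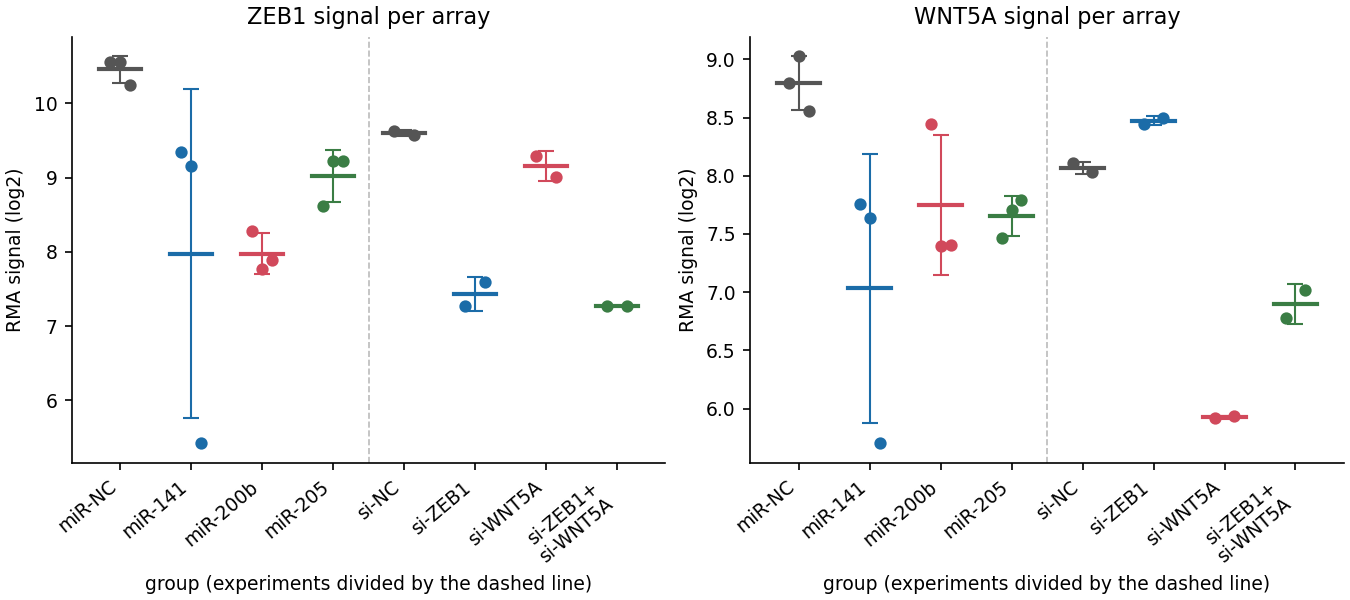
ZEB1 and WNT5A signal (log2, vertical axis) in each of the 20 arrays by group, 1 point an array with the group mean. Every miRNA array lies below every miR-NC array for both genes, and miR-141 replicate 3 reads 5.42 for ZEB1.

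miR-141 against miR-NC asks what this member of the miR-200 family changes. The oncogenic transcription factor MYC fell most, from 11.10 ± 0.29 to 4.58 ± 1.60 (SD, n = 3 each; −6.53 ± 0.62, adjusted p = 0.000228). The splicing regulators SNRNP40 (−5.63 ± 0.68) and HNRNPL (−5.21 ± 0.28, adjusted p = 3.53e-06) and the chromatin protein RBBP4 (−4.76 ± 0.96, or −0.78 with adjusted p = 0.0624 over the mean of its probe sets) followed. Interleukin-8, CXCL8 (−4.63 ± 0.35, adjusted p = 6.6e-05), the mitochondrial import receptor TOMM22 (−4.60), thrombospondin 1, THBS1 (−4.54 ± 0.58), the tetraspanin CD9 (−4.30), RDH10 (−4.08) and DCAF17 (−3.99) also fell. ZBED2, a transcription factor, rose most, from 2.54, near background, to 6.34 (3.79 ± 0.38, adjusted p = 0.000264). The other largest rises were GALNT16 (3.03), ANGPTL4, FAM53A (2.98), the nuclear lamin gene LMNA (2.98 ± 0.34), SEMA3F (2.94), ARHGEF37 (2.90), the desmosome gene PKP3 (2.86 ± 0.30), SYCE1L (2.85) and SPOCD1 (2.80). Each of these genes had all 3 miR-141 arrays beyond all 3 control arrays. Of 19775 genes, 2997 were higher and 1888 lower, and 1900 and 1561 of them moved at least 2-fold. With each array centred on its median 2063 were higher and 2101 lower, without the excess of rises, and after quantile normalization 3279 and 1734. The total of 4885 became 2688 without miR-NC replicate 2.

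The epithelial list moved up with miR-141 (15 higher and 1 lower of 44, and 16 and 1 adjusted over the list alone; adjusted p = 0.00226, and adjusted p = 0.129 with an estimated correlation). Its median was 0.58. Blood cell and endothelial markers, not expected in this line, had medians of 0.43 and 0.44 and passed by fry but not by camera (adjusted p = 0.31 and 0.63). With miR-200b these 3 medians were 0.41, 0.15 and 0.18, and with miR-205 0.37, 0.25 and −0.01. In the epithelial list the epithelial splicing regulator ESRP1 rose (1.97 ± 0.22, adjusted p = 0.000322), as did the lipid enzyme gene CDS1 (2.67 ± 0.37, adjusted p = 0.000783). The reported miR-200 family targets moved down (4 higher and 11 lower of 30, and 6 and 13 adjusted over the list alone; adjusted p = 0.00667, and adjusted p = 0.441 with an estimated correlation), with the ubiquitin ligase adaptor KLHL20 at −2.14 ± 0.22 (adjusted p = 0.000293). The mean of all probe sets of KLHL20 was −0.39 (adjusted p = 0.216). The reported miR-205 targets moved down as well (4 higher and 11 lower of 24, and 5 and 16 adjusted over the list alone; adjusted p = 0.000823, and adjusted p = 0.129 with an estimated correlation), with the signal transducer SMAD1 at −1.76 ± 0.26 (adjusted p = 0.00102). The inflammatory list moved down (3 higher and 9 lower of 24, and 3 and 11 adjusted over the list alone; adjusted p = 0.00321, and adjusted p = 0.441 with an estimated correlation), with the cytokine IL6 at −2.75 ± 0.31 (adjusted p = 0.000322). The mesenchymal list went both ways (7 higher and 9 lower of 45, and 7 and 10 adjusted over the list alone; adjusted p = 0.243). The lysyl oxidase LOX fell (−1.56 ± 0.25, adjusted p = 0.00161) and its relative LOXL2 rose (1.82 ± 0.26, adjusted p = 0.000822).

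The lists below moved down with miR-141, but missed the threshold without its replicate 3. The actin and focal adhesion list (1 higher and 8 lower of 40, and 1 and 8 adjusted over the list alone; adjusted p = 0.000823, and adjusted p = 0.732 with an estimated correlation) included the integrin ITGB1 (−1.50 ± 0.23, adjusted p = 0.00117). The TGF-beta list (3 higher and 8 lower of 28, and 5 and 10 adjusted over the list alone; adjusted p = 0.0352, and adjusted p = 0.534 with an estimated correlation) included the repressor TGIF1 (−3.65 ± 0.47, adjusted p = 0.00049). The mitosis list (3 higher and 10 lower of 35, and 3 and 11 adjusted over the list alone; adjusted p = 0.00667, and adjusted p = 0.732 with an estimated correlation) included the mitotic motor KIF20A (−2.12 ± 0.37, adjusted p = 0.0022). The unfolded protein and ATF4 list had 7 higher and 11 lower of 30, and 9 and 12 adjusted over the list alone (adjusted p = 0.0361, and adjusted p = 0.688 with an estimated correlation). Without miR-141 replicate 3 the adjusted p of these lists was 0.162, 0.0936, 0.1 and 0.196, in that order. It was 0.755, 0.26, 0.31 and 0.313 without the 3 arrays of low 5′ signal, a test of replicate 1 alone that assumes it varies like the other groups. Without miR-NC replicate 3 it was 0.0671 for the TGF-beta list and 0.0926 for the unfolded protein list.

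miR-200b against miR-NC asks the same of a family member with another seed. ZBED2 again rose most, from 2.54, near background, to 6.88 (4.33 ± 0.38, adjusted p = 0.000147), so the size is uncertain. The proteasome gene PSMC3 (3.95 ± 0.97, adjusted p = 0.0202), GIT1 (3.69), CASKIN1 (3.57), the actin nucleation subunit ARPC4 (3.42 ± 0.38, adjusted p = 0.000538), PKP3 (3.33 ± 0.30), XYLT2 (3.10), the chaperone partner CDC37 (3.09 ± 0.77, adjusted p = 0.0213), SPECC1L (3.08) and CDS1 (3.02 ± 0.37) rose too. PSMC3 was lost without miR-NC replicates 1 and 2 and miR-200b replicates 1 and 2 (adjusted p = 0.0824, 0.0799, 0.0709 and 0.0856), and CDC37 without the same arrays (adjusted p = 0.0684, 0.0941, 0.0757 and 0.0937). With the GAPDH covariate PSMC3 was 0.96 (adjusted p = 0.257) and CDC37 0.73 (adjusted p = 0.285). HNRNPL fell most (−4.56 ± 0.28, adjusted p = 1.78e-05), followed by CXCL8 (−4.37 ± 0.35, adjusted p = 7.71e-05), FN1, MYC (−3.67 ± 0.62, adjusted p = 0.00362) and the axon guidance ligand SEMA3C (−3.60 ± 0.43). THBS1 (−3.46), PRPF39 (−3.38), DNAAF2 (−3.18), EEIG2 (−3.08) and TNFRSF11B, which encodes osteoprotegerin (−3.03), completed the largest falls. Of 19775 genes, 1377 were higher and 963 lower, and 1054 and 731 moved at least 2-fold. The total of 2340 became 1323 without miR-NC replicate 1, 970 without miR-NC replicate 2, 920 without miR-200b replicate 2 and 4634 without miR-141 replicate 3. A fit with the GAPDH covariate called 3335 genes, among them 1335 of the 2340.

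The epithelial list moved up with miR-200b and none of its genes was called lower (11 higher of 44, and 14 adjusted over the list alone; adjusted p = 0.000566, and adjusted p = 0.129 with an estimated correlation). ESRP1 (2.78 ± 0.22, adjusted p = 7.71e-05) and the protease inhibitor SPINT2 (2.40 ± 0.31, adjusted p = 0.00101) rose in it. The mesenchymal list moved down (1 higher and 9 lower of 45, and 1 and 10 adjusted over the list alone; adjusted p = 0.0205, and adjusted p = 0.598 with an estimated correlation), a call lost without miR-200b replicate 1 (adjusted p = 0.0619) and with the GAPDH difference as a covariate (adjusted p = 0.0612). LOX fell in it (−2.97 ± 0.25, adjusted p = 0.000147) and LOXL2 rose (1.54 ± 0.26, adjusted p = 0.00341), although the mean of the LOXL2 probe sets did not pass (0.42, adjusted p = 0.161). The reported miR-200 family targets moved down (4 higher and 9 lower of 30, and 4 and 13 adjusted over the list alone; adjusted p = 0.000207, and adjusted p = 0.199 with an estimated correlation), with KLHL20 at −2.04 ± 0.22 (adjusted p = 0.000468) and the vesicle coat gene SEC23A at −1.99 ± 0.28 (adjusted p = 0.00147). The reported miR-205 targets moved down (2 higher and 7 lower of 24, and 2 and 10 adjusted over the list alone; adjusted p = 0.00601, and adjusted p = 0.199 with an estimated correlation), with SMAD1 at −1.31 ± 0.26 (adjusted p = 0.00803) and at −0.65 over the mean of its probe sets (adjusted p = 0.138). The inflammatory list moved down (2 higher and 7 lower of 24, and 3 and 9 adjusted over the list alone; adjusted p = 0.00667, and adjusted p = 0.499 with an estimated correlation), with IL6 at −2.83 ± 0.31 (adjusted p = 0.000542) and the chemokine CXCL3 at −2.31 ± 0.23 (adjusted p = 0.000265).

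miR-205 against miR-NC asks what a miRNA outside the family changes. MYC (−5.46 ± 0.62, adjusted p = 0.000245), HNRNPL (−5.46 ± 0.28, adjusted p = 2.06e-06), CXCL8 (−4.92 ± 0.35, adjusted p = 2.42e-05) and THBS1 (−4.75 ± 0.58, adjusted p = 0.000334) fell most. SNRNP40 (−4.15), CD9 (−4.03), TLNRD1 (−4.00), SIPA1L3 (−3.84), PRPF39 (−3.83) and RBBP4 (−3.80 ± 0.96, adjusted p = 0.0148) followed, RBBP4 being lost without miR-NC replicate 2 or miR-205 replicate 1 (adjusted p = 0.0642 and 0.0752) or over the mean of its probe sets (−0.74, adjusted p = 0.0837). ZBED2 (3.87 ± 0.38, adjusted p = 0.00013), PKP3 (3.19), the epidermal gene SCEL (3.18), LMNA (3.13) and GIT1 (3.56) rose. So did PSMC3 (4.89 ± 0.97, adjusted p = 0.00409), the DNA polymerase POLM (3.46), the actin bundler LCP1 (3.22), the ubiquitin-conjugating enzyme UBE2S (3.28 ± 0.87, adjusted p = 0.018) and CIMIP2A (3.26 ± 0.93, adjusted p = 0.025). These 5 did not pass with the GAPDH difference as a covariate, at 1.30 (adjusted p = 0.172), 1.06 (adjusted p = 0.189), 0.54 (adjusted p = 0.397), 0.07 (adjusted p = 0.94) and −0.18 (adjusted p = 0.86) in that order. The miR-205 and miR-NC arrays do not overlap in the GAPDH difference, so these adjusted values are extrapolations. UBE2S was also lost without miR-NC replicates 1 and 2 and miR-205 replicates 1 and 2 (adjusted p = 0.0674, 0.0761, 0.0782 and 0.058). CIMIP2A was lost without any miR-NC array and without miR-205 replicates 1 and 2 (adjusted p = 0.0721, 0.0765, 0.0585, 0.0864 and 0.084). Of 19775 genes, 2875 were higher and 1425 lower, and 1995 and 1119 moved at least 2-fold. The total of 4300 became 2467 without miR-NC replicate 2, 2116, 2814 and 2758 without miR-205 replicate 1, 2 or 3, and 6975 without miR-141 replicate 3. With the GAPDH covariate 1729 genes were higher and 1605 lower, among them 1972 of the 4300.

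In the epithelial list 9 of 44 genes were higher and none lower with miR-205, and the same count held adjusted over the list alone, but the list did not pass (adjusted p = 0.1). The keratins KRT7 (2.21 ± 0.28, adjusted p = 0.000374), KRT8 (2.38 ± 0.43, adjusted p = 0.00247) and KRT18 (1.71 ± 0.28, adjusted p = 0.00141) rose. With the GAPDH covariate KRT8 (1.05, adjusted p = 0.107) and KRT18 (1.09, adjusted p = 0.0503) missed the threshold. The mesenchymal gene LOXL2 rose (2.44 ± 0.26, adjusted p = 0.000192). The reported miR-205 targets moved down (2 higher and 9 lower of 24, and 2 and 11 adjusted over the list alone; adjusted p = 0.000566, and adjusted p = 0.129 with an estimated correlation), with the chromatin protein HMGB3 at −2.85 ± 0.36 (adjusted p = 4e-04) and SMAD1 at −2.11 ± 0.26 (adjusted p = 0.00035). The mean of the SMAD1 probe sets was −0.63 (adjusted p = 0.106). The reported miR-200 family targets moved down (6 higher and 7 lower of 30, and 7 and 10 adjusted over the list alone; adjusted p = 0.0345, and adjusted p = 0.594 with an estimated correlation), with KLHL20 at −1.96 ± 0.22 (adjusted p = 0.000224), a list call lost without miR-205 replicate 1 (adjusted p = 0.058). The mitosis list moved down (2 higher and 7 lower of 35, also adjusted over the list alone; adjusted p = 0.00667, and adjusted p = 0.73 with an estimated correlation), with KIF20A at −2.09 ± 0.37 (adjusted p = 0.00222). The inflammatory list moved down (4 higher and 7 lower of 24, and 5 and 7 adjusted over the list alone; adjusted p = 0.0252, and adjusted p = 0.594 with an estimated correlation), with IL6 at −2.93 ± 0.31 (adjusted p = 0.000208). That call was lost without miR-NC replicate 3 (adjusted p = 0.071).

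Genes moved the same way by all 3 miRNAs address what miRNAs of unlike sequence share. MYC, HNRNPL, CXCL8 and THBS1 were among the largest falls of every miRNA, joined by the splicing factor PRPF39 (−3.81, −3.38 and −3.83 with miR-141, miR-200b and miR-205) and DNAAF2 (−3.37, −3.18 and −3.09). ZBED2, from a miR-NC signal near background, and PKP3 led the shared rises. SPECC1L (2.46, 3.08 and 2.68), LMNA (2.98, 2.42 and 3.13), the SMAD partner FOXH1 (2.57, 2.37 and 2.57) and the stress kinase MAPKAPK3 (2.34, 2.92 and 2.57) rose with each. In total 1471 genes were called alike, 859 higher where independent lists of these sizes would share 30.3 and 612 lower where they would share 6.6. Pairs shared 934 higher and 682 lower genes (miR-141 and miR-200b), 1810 and 1129 (miR-141 and miR-205) and 1149 and 701 (miR-200b and miR-205), and 7 genes were called in opposite directions by some pair. The total of 1471 became 867 without miR-NC replicate 1, 598 without miR-NC replicate 2, 2752 without miR-141 replicate 3, 664 without miR-200b replicate 2 and 978 without miR-205 replicate 1. With the GAPDH covariate 1003 genes were shared higher and 1055 lower, among them 897 of the 1471.

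The miR-NC arrays, shared by all comparisons, may cause part of the excess. Across genes, which are not independent replicates, the changes with miR-141 and miR-200b, miR-141 and miR-205, and miR-200b and miR-205 correlated with r = 0.697, 0.781 and 0.795. Unchanged simulated groups gave 0.5 and, in 100 draws, no shared call. Covariances were 0.405, 0.539 and 0.423 against 0.071 simulated. Draws without changed genes cannot size the controls' part.

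**Figure D3:**
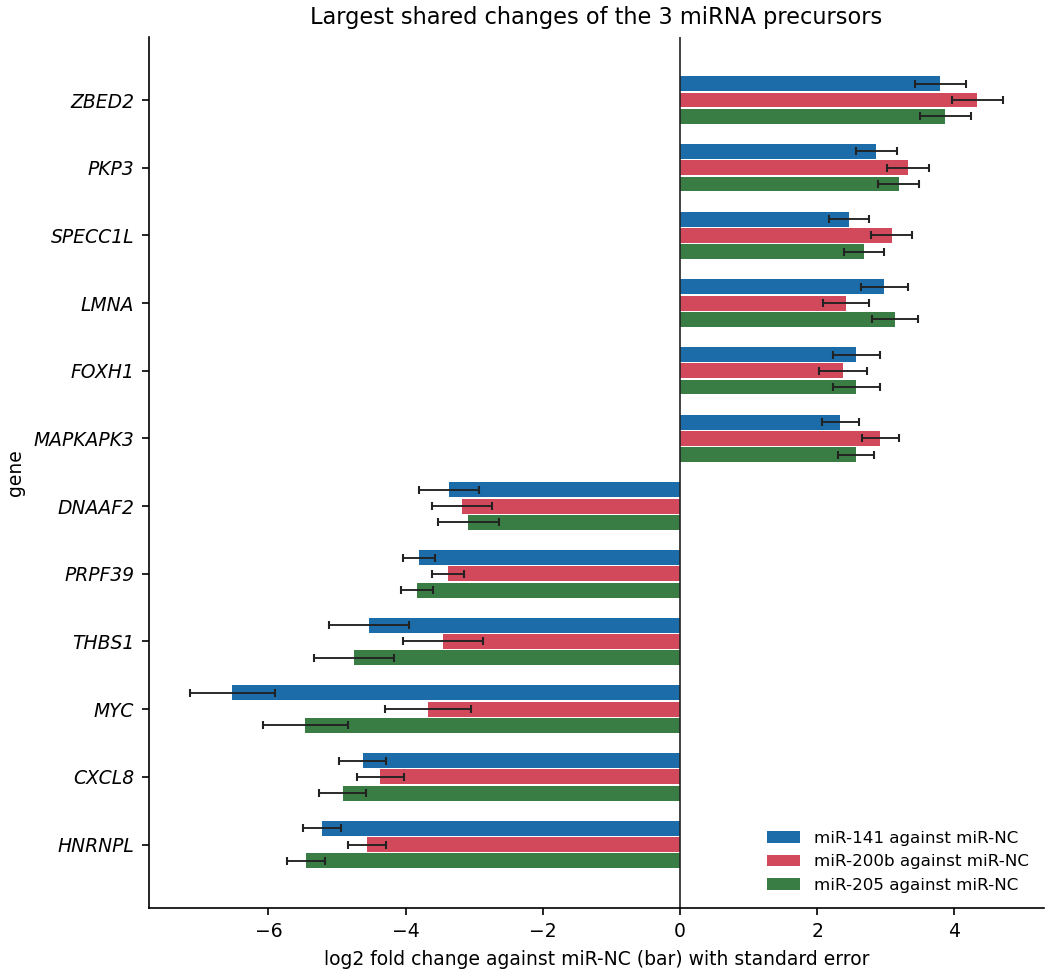
Change from miR-NC (log2, horizontal axis) with each of the 3 miRNAs for the 12 genes with the largest shared rises and falls, 1 bar a miRNA with the SE of the fit. ZBED2, near background with miR-NC, lay at 3.79 to 4.33 and HNRNPL at −4.56 to −5.46.

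miR-200b and miR-141, which share a family, were compared directly. The acid-sensing receptor gene GPR65 was higher with miR-200b (2.97 ± 0.22, adjusted p = 0.000182), and SPOCD1 was lower (−3.12 ± 0.42, adjusted p = 0.00771). Higher too were FHIP1A (2.88 ± 0.67, adjusted p = 0.0447), MYC (2.85 ± 0.62, adjusted p = 0.0402) and the cofactor enzyme GCH1 (2.79 ± 0.54, adjusted p = 0.0279). Lower were DNAI4 (−2.59 ± 0.44, adjusted p = 0.0196), GALNT16 (−2.46 ± 0.47, adjusted p = 0.0279) and the collagen COL1A1 (−2.45 ± 0.55, adjusted p = 0.043). FHIP1A, MYC, GCH1, GALNT16 and COL1A1 were lost without miR-141 replicate 2 or miR-200b replicate 1 or 2, COL1A1 also without miR-141 replicate 3, and DNAI4 without miR-141 replicate 2 or miR-200b replicate 1. In these fits their adjusted p lay between 0.0618 and 0.161. With the GAPDH covariate FHIP1A (1.80), MYC (2.24), GCH1 (2.15), DNAI4 (−2.49) and GALNT16 (−1.70) missed the threshold (adjusted p between 0.0659 and 0.13). In total 129 genes were higher and 332 lower. The count varied with the setting, up to 2986 with all 20 arrays in 1 fit, with 54 called when the GAPDH difference was a covariate, 61 without the 3 arrays of low 5′ signal (1 miR-141 array) and 0 by limma with only the arrays compared. Another split of these 6 arrays, which follows the low 5′ signal, called 785 genes. With centring 106 were higher and 138 lower. The 461 became 2549, 36 and 716 without miR-141 replicate 1, 2 or 3 and 26, 39 and 739 without miR-200b replicate 1, 2 or 3.

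The actin list was higher with miR-200b than with miR-141 (0 higher and 1 lower of 40, and 1 and 1 adjusted over the list alone; adjusted p = 0.0148, and adjusted p = 0.74 with an estimated correlation). The p53 list (0 higher and 1 lower of 25, and 4 and 2 adjusted over the list alone; adjusted p = 0.0409, and adjusted p = 0.688 with an estimated correlation) and the unfolded protein list (1 higher and 0 lower of 30, and 3 and 0 adjusted over the list alone; adjusted p = 0.00321, and adjusted p = 0.594 with an estimated correlation) were higher as well. Without miR-141 replicate 3 none passed (adjusted p = 0.972, 0.336 and 0.0595). The actin and p53 lists were also lost with the GAPDH difference as a covariate (adjusted p = 0.986 and 0.222) and without the 3 arrays of low 5′ signal, with replicate 1 as the only miR-141 array (adjusted p = 0.671 and 0.57). The actin list was also lost without miR-200b replicate 1 (adjusted p = 0.0851) and the p53 list without miR-200b replicate 1, 2 or 3 (adjusted p = 0.0619, 0.06 and 0.05).

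miR-205 and miR-141 differed in the call of 1 gene, the RNA-binding protein gene RBPMS2, at 5.22 ± 0.12 against 7.27 ± 0.36 (SD, n = 3 each; −2.05 ± 0.23, adjusted p = 0.0192). At an unadjusted p under 0.05 there were 2638 genes. RBPMS2 was lost without miR-141 replicate 2 (adjusted p = 0.175) and without miR-205 replicate 1, 2 or 3 (adjusted p = 0.251, 0.227 and 0.148), where limma called 0 genes, and 920 and 7 genes were called without miR-141 replicate 1 or 3. Across genes, miR-141 replicate 1 correlated with the miR-205 arrays at r = 0.993 to 0.995, where they correlated with one another at 0.994 to 0.997. With miR-141 replicates 2 and 3 its correlations were 0.989 and 0.919. The epithelial list was lower with miR-205 than with miR-141 (0 of 44 genes called and 8 at an unadjusted p under 0.05, and 0 higher and 3 lower adjusted over the list alone; adjusted p = 0.0361, and adjusted p = 0.374 with an estimated correlation). The actin list (0 of 40 genes called, also adjusted over the list alone, and 11 at an unadjusted p under 0.05; adjusted p = 0.000158, and adjusted p = 0.73 with an estimated correlation) and the p53 list (0 of 25 called and 6 at an unadjusted p under 0.05, and 3 higher adjusted over the list alone; adjusted p = 0.0148, and adjusted p = 0.604 with an estimated correlation) were higher. Without miR-141 replicate 3 none of these lists passed (adjusted p = 0.0794, 0.0718 and 0.0688), nor did they without the 3 arrays of low 5′ signal (adjusted p = 0.176, 0.919 and 0.0882). There replicate 1, close to miR-205, is the only miR-141 array. The medians of the blood cell and endothelial markers were −0.17 and −0.28 in this comparison, with no pass by camera or fry, against −0.22 for the epithelial list. The epithelial list was also lost without miR-205 replicate 3 (adjusted p = 0.0606), and the actin list with the GAPDH difference as a covariate (adjusted p = 0.52).

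miR-205 and miR-200b differed most in FN1, which was 11.38 ± 0.19 against 8.21 ± 0.83 (SD, n = 3 each; 3.17 ± 0.39, adjusted p = 0.0049). The intermediate filament gene NES (2.58 ± 0.47, adjusted p = 0.0253), DISP2 (2.47 ± 0.28, adjusted p = 0.00294) and the noncoding RNA BLACAT1 (2.43 ± 0.30, adjusted p = 0.0049) were higher with miR-205. LSM12 (−2.53 ± 0.49, adjusted p = 0.0312), the desmosome-linked gene KAZN (−2.25 ± 0.21, adjusted p = 0.0025), SPINT2 (−2.19 ± 0.31, adjusted p = 0.00963) and the MYC antagonist MXD1 (−2.08 ± 0.30, adjusted p = 0.00963) were lower. NES was lost without miR-200b replicate 2 or 3 or any miR-205 array, LSM12 without any of the 6 arrays, SPINT2 without any miR-205 array and MXD1 without miR-205 replicate 1 or 3, with adjusted p between 0.0545 and 0.162. The mean of the KAZN probe sets did not pass (−0.20, adjusted p = 0.715). In total 117 genes were higher and 64 lower, or 88 and 90 after quantile normalization. These 181 became 33 and 37 without miR-200b replicate 1 or 2, 18, 23 and 20 without miR-205 replicate 1, 2 or 3, and 1403 without miR-141 replicate 3.

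The epithelial list was lower with miR-205 than with miR-200b (0 higher and 3 lower of 44, and 0 and 6 adjusted over the list alone; adjusted p = 0.0191, and adjusted p = 0.269 with an estimated correlation), a call lost without miR-200b replicate 1 (adjusted p = 0.106). The mesenchymal list was higher (3 higher and 0 lower of 45, and 11 and 1 adjusted over the list alone; adjusted p = 0.0131, and adjusted p = 0.594 with an estimated correlation). The unfolded protein list was lower (0 higher and 1 lower of 30, and 0 and 3 adjusted over the list alone; adjusted p = 0.0129, and adjusted p = 0.604 with an estimated correlation). The miR-200 family targets were higher with miR-205 (2 higher and 0 lower of 30, and 4 and 0 adjusted over the list alone; adjusted p = 0.0451, and adjusted p = 0.594 with an estimated correlation). The miR-205 targets were lower (0 higher and 1 lower of 24, and 3 and 7 adjusted over the list alone; adjusted p = 0.0451, and adjusted p = 0.441 with an estimated correlation). The miR-200 target call was lost without replicate 2 or 3 of any of the 4 groups (adjusted p between 0.0501 and 0.132), with the GAPDH difference as a covariate (adjusted p = 0.0815) and without the 3 arrays of low 5′ signal (adjusted p = 0.122). The miR-205 target call was lost without miR-141 replicate 1 or 3, miR-200b replicate 1 or 2, or miR-205 replicate 1 or 3 (adjusted p between 0.0507 and 0.24).

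si-ZEB1 against si-NC asks what the loss of ZEB1 alone changes. ZEB1 fell from 9.60 ± 0.04 to 7.44 ± 0.23 (SD, n = 2 each; −2.16 ± 0.13, adjusted p = 1.28e-05). The zinc finger gene ZNF165 rose most (3.41 ± 0.12, adjusted p = 2.09e-06), with SCEL (3.15), MPZL3 (3.13), NHLRC3 (2.93), SPINT2 (2.91 ± 0.10), ZBED2 (2.90 ± 0.14), the pentraxin PTX3 (2.88 ± 0.12), MCOLN3 (2.86), CPEB3 (2.74) and VXN (2.71). The largest falls were SNTB1 (−3.04 ± 0.17, adjusted p = 9.9e-06), the Notch coactivator MAML3 (−2.90 ± 0.16), SYTL2 (−2.89 ± 0.11), KCNS3 (−2.81), TMEM158 (−2.79 ± 0.12), FKBP5 (−2.61), CLMP (−2.57), FAM107B (−2.52), CHRAC1 (−2.50) and the Notch target HES1 (−2.50 ± 0.11, adjusted p = 5.19e-06). CDH1 (2.94 against 3.10) and VIM (0.12, adjusted p = 0.285) were not called, nor were ZEB2 (−0.31, adjusted p = 0.374) and FN1 (−0.35 ± 0.14, adjusted p = 0.0898). Of the 4 other ZEB2 probe sets 3 fell (−1.60, −0.60 and −0.47, adjusted p = 0.000555, 0.0107 and 0.0448), and the dimmer VIM probe set rose (0.97, adjusted p = 0.00815). CDH2 fell (−0.39 ± 0.11, adjusted p = 0.0219), a call lost without any of the 4 arrays (adjusted p between 0.0638 and 0.118). WNT5A rose (0.40 ± 0.10, adjusted p = 0.0124), a call lost without si-NC replicate 2 (adjusted p = 0.0813) or si-ZEB1 replicate 2 (adjusted p = 0.0656), and its other probe set pointed down (−0.32, adjusted p = 0.217). Of 19775 genes, 3067 were higher and 3378 lower, and 406 and 526 moved at least 2-fold.

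The DNA replication list moved down with si-ZEB1 (2 higher and 18 lower of 40, and 2 and 23 adjusted over the list alone; adjusted p = 0.000977, and adjusted p = 0.657 with an estimated correlation), with the ribonucleotide reductase subunit RRM2 at −1.84 ± 0.09 (adjusted p = 7.34e-06). The cholesterol synthesis list moved up (10 higher and 1 lower of 18, also adjusted over the list alone; adjusted p = 0.00145, and adjusted p = 0.626 with an estimated correlation), with the reductase DHCR7 at 1.35 ± 0.08 (adjusted p = 1.29e-05). The inflammatory list moved up (14 higher and 5 lower of 24, and 15 and 6 adjusted over the list alone; adjusted p = 0.00653, and adjusted p = 0.626 with an estimated correlation). The chemokine CXCL2 (2.06 ± 0.11, adjusted p = 9.29e-06) and the adhesion receptor ICAM1 (1.95 ± 0.14, adjusted p = 2.95e-05) rose in it, while the cytokine IL1B fell (−2.01 ± 0.13, adjusted p = 1.48e-05). The p53 list moved up (6 higher and 0 lower of 25, also adjusted over the list alone; adjusted p = 0.0358, and adjusted p = 0.657 with an estimated correlation), with the death receptor FAS at 1.13 ± 0.08 (adjusted p = 2.52e-05). That list call was lost without si-NC replicate 2 (adjusted p = 0.126) or si-ZEB1 replicate 2 (adjusted p = 0.0806). The epithelial list had 14 higher and 4 lower genes of 44, also adjusted over the list alone, without passing (adjusted p = 0.084), among them CDS1 (2.36 ± 0.11, adjusted p = 5.18e-06) and PKP3 (1.33 ± 0.10, adjusted p = 2.81e-05). The mesenchymal list had 13 higher and 9 lower of 45, and 15 and 12 adjusted over the list alone (adjusted p = 0.311), and LOX rose in it (2.47 ± 0.09, adjusted p = 2.09e-06). ID1, a target of BMP and TGF-beta signals, fell (−2.15 ± 0.08, adjusted p = 3.26e-06).

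si-WNT5A against si-NC asks the same of WNT5A. WNT5A fell from 8.07 ± 0.05 to 5.93 ± 0.01 (SD, n = 2 each; −2.14 ± 0.10, adjusted p = 0.000166). The collagen-binding integrin ITGA2 (−1.97 ± 0.13, adjusted p = 0.000264), SEMA3C (−1.74 ± 0.18, adjusted p = 0.0014), SCEL (−1.65), ERGIC2 (−1.64), the ephrin receptor EPHB1 (−1.60 ± 0.14), AFAP1L2 (−1.57), MAMDC2 (−1.56), SLC4A4 (−1.45) and TENM2 (−1.43 ± 0.09) fell. The fatty acid carrier FABP4 (1.75 ± 0.11, adjusted p = 0.000236), SCG5 (1.66 ± 0.10), the Toll-like receptor partner LY96 (1.55 ± 0.15), SEL1L3 (1.50), PPP2R1B (1.43), ICA1-AS1 (1.41), DCLK1 (1.39), MSR1 (1.34), LZTFL1 (1.32) and ZNF404 (1.26) rose. ZEB1 was lower in both arrays without passing (−0.45 ± 0.13, adjusted p = 0.0816), and 1 of its other 3 probe sets passed (−0.39, adjusted p = 0.0353). CDH1 (0.03), VIM (−0.08), CDH2 (−0.13), FN1 (−0.27) and ZEB2 (−0.23) were not called, while the dimmer VIM probe set fell (−1.07, adjusted p = 0.0261). Of 19775 genes, 699 were higher and 623 lower, and 40 and 53 moved at least 2-fold. The total of 1322 became 384 and 343 without si-NC replicate 1 or 2 and 663 and 479 without si-WNT5A replicate 1 or 2.

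The mesenchymal list moved down with si-WNT5A (1 higher and 12 lower of 45, and 1 and 13 adjusted over the list alone; adjusted p = 2.41e-06, and adjusted p = 0.315 with an estimated correlation), with the fibroblast protease FAP at −1.06 ± 0.09 and the fibrillin FBN1 at −0.95 ± 0.08 (adjusted p = 0.000791 each). The TGF-beta list moved down (1 higher and 5 lower of 28, and 4 and 9 adjusted over the list alone; adjusted p = 0.000977, and adjusted p = 0.626 with an estimated correlation). In it PMEPA1 (−0.64 ± 0.09, adjusted p = 0.0056) was lost without si-NC replicate 2 (adjusted p = 0.0577) and TGIF1 (−0.70 ± 0.11, adjusted p = 0.00682) without si-NC replicate 1 (adjusted p = 0.0641). The actin list moved down (0 higher and 2 lower of 40, also adjusted over the list alone; adjusted p = 0.000977, and adjusted p = 0.626 with an estimated correlation). The mitosis list moved down (0 higher and 3 lower of 35, and 0 and 4 adjusted over the list alone; adjusted p = 0.0146, and adjusted p = 0.626 with an estimated correlation), with the centromere protein CENPF at −0.51 ± 0.08 (adjusted p = 0.00857). CENPF was lost without si-NC replicate 1 or 2 or si-WNT5A replicate 2 (adjusted p = 0.0659, 0.0808 and 0.0575). The DNA replication list moved down (1 higher and 2 lower of 40, also adjusted over the list alone; adjusted p = 0.0311, and adjusted p = 0.699 with an estimated correlation), a call lost without si-NC replicate 2 (adjusted p = 0.205) or si-WNT5A replicate 1 (adjusted p = 0.343).

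Cholesterol synthesis moved down with si-WNT5A (1 higher and 3 lower of 18, and 1 and 6 adjusted over the list alone; adjusted p = 0.0017, and adjusted p = 0.626 with an estimated correlation). The synthase HMGCS1 fell in it (−0.58 ± 0.11, adjusted p = 0.0202) but was lost without si-NC replicate 1 or 2 or si-WNT5A replicate 2 (adjusted p = 0.126, 0.097 and 0.114). The p53 list moved up (5 higher and 1 lower of 25, and 6 and 1 adjusted over the list alone; adjusted p = 0.000977, and adjusted p = 0.626 with an estimated correlation), with the stress gene SESN1 at 0.69 ± 0.08 (adjusted p = 0.00227), a list call lost without si-WNT5A replicate 1 (adjusted p = 0.0749). The miR-200 family targets moved down (0 higher and 2 lower of 30, also adjusted over the list alone; adjusted p = 0.0201, and adjusted p = 0.626 with an estimated correlation), a call lost without si-WNT5A replicate 2 (adjusted p = 0.292). IL1B rose (1.15 ± 0.13, adjusted p = 0.00172), and none of the 44 epithelial genes was called by limma, where 2 had an unadjusted p under 0.05. Among Wnt genes the ligand WNT5B (−0.66 ± 0.08, adjusted p = 0.00286) and the polarity gene VANGL1 (−0.64 ± 0.09, adjusted p = 0.00439) fell.

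Both siRNAs together against si-NC ask what the joint loss changes. ZEB1 fell to 7.27 (−2.33 ± 0.13, adjusted p = 2.56e-05) and WNT5A to 6.90 ± 0.17 (SD, n = 2; −1.17 ± 0.10, adjusted p = 0.000106), where si-WNT5A alone gave 5.93, a difference that was not tested. CDH2 fell (−0.69 ± 0.11, adjusted p = 0.00189), as did FN1 (−0.57 ± 0.14, adjusted p = 0.0168). The FN1 call was lost without any of the 4 arrays (adjusted p between 0.0568 and 0.0751). Its other probe sets passed (adjusted p up to 0.00896) except that at −0.31. CDH1 (−0.23, adjusted p = 0.229), VIM (0.08) and ZEB2 (0.08) were not called, while 1 of the 4 other ZEB2 probe sets fell (−1.12, adjusted p = 0.00522). ZNF165 rose most (3.62 ± 0.12, adjusted p = 1.43e-05), with VXN (2.65), CPEB3 (2.60), the cell polarity gene PARD6B (2.45 ± 0.25), SPINT2 (2.36 ± 0.10), LINC03011 (2.30), MPZL3 (2.30), PTX3 (2.29), SCEL (2.27) and ZBED2 (2.23). SYTL2 fell most (−2.75 ± 0.11, adjusted p = 1.43e-05), with HES1 (−2.49 ± 0.11), KCNS3 (−2.40), the neural adhesion molecule NCAM1 (−2.26 ± 0.15), FAM200C (−2.21), SLC37A2 (−2.20), SNTB1 (−2.10), LINC02910 (−2.04) and NREP (−2.04). Of 19775 genes, 3115 were higher and 2557 lower, and 243 and 295 moved at least 2-fold. The total of 5672 became 3328 and 3362 without si-NC replicate 1 or 2.

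The inflammatory list moved up with both siRNAs (13 higher and 3 lower of 24, and 15 and 4 adjusted over the list alone; adjusted p = 0.00396, and adjusted p = 0.626 with an estimated correlation), with CXCL2 at 2.10 ± 0.11 (adjusted p = 2.5e-05). Cholesterol synthesis moved up (8 higher and 1 lower of 18, and 8 and 2 adjusted over the list alone; adjusted p = 0.0341, and adjusted p = 0.626 with an estimated correlation), with DHCR7 at 0.87 ± 0.08 (adjusted p = 0.000173). That list call was lost without si-NC replicate 2 (adjusted p = 0.0813) or the double transfection's replicate 2 (adjusted p = 0.0528). The TGF-beta list moved down (3 higher and 10 lower of 28, and 3 and 12 adjusted over the list alone; adjusted p = 0.0358, and adjusted p = 0.626 with an estimated correlation), with ID1 at −1.86 ± 0.08 (adjusted p = 1.9e-05) and the matrix gene TGFBI at −0.97 ± 0.09 (adjusted p = 0.000156). It was lost without si-NC replicate 1 (adjusted p = 0.0622) or the double transfection's replicate 1 (adjusted p = 0.0931). The epithelial list had 14 higher and 1 lower of 44 genes, and 15 and 2 adjusted over the list alone, without passing (adjusted p = 0.0986), among them CDS1 (1.97 ± 0.11, adjusted p = 2.5e-05) and the membrane trafficking gene MAL2 (2.10 ± 0.18, adjusted p = 0.000126). LOX rose as with si-ZEB1 alone (1.85 ± 0.09, adjusted p = 1.9e-05).

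The interaction asks whether a siRNA acts differently when the other is present. The Toll-like receptor partner LY96 had the lowest value (−3.22 ± 0.22, adjusted p = 0.00154), with changes of 0.11 with si-ZEB1, 1.55 with si-WNT5A and −1.56 with both. The secretory chaperone gene SCG5 (−2.59 ± 0.14, adjusted p = 0.000862) changed by −0.22, 1.66 and −1.15. The epidermal gene FLG (−2.38 ± 0.27, adjusted p = 0.00357) and the noncoding RNA FTX (−2.06 ± 0.32, adjusted p = 0.00737) rose with si-ZEB1 alone (2.21 and 1.67). TMEM158 (2.39 ± 0.18, adjusted p = 0.00154) and the cell cycle gene RGCC (2.33 ± 0.28, adjusted p = 0.00393) fell with each siRNA (−2.79 and −1.18 for TMEM158, −2.10 and −1.10 for RGCC), but with both by less than with si-ZEB1 alone (−1.58 and −0.87). PLEKHA3 (1.86 ± 0.17, adjusted p = 0.0019) and TMCC3 (1.70 ± 0.24, adjusted p = 0.00585) fell with si-WNT5A alone (−1.38 and −1.22). WNT5A itself had an interaction of 0.57 ± 0.14 (adjusted p = 0.0313). In total 1314 genes had a positive and 1138 a negative interaction, and 149 and 172 of these were at least 2-fold. The total of 2452 became 880 and 943 without si-NC replicate 1 or 2, 1152 without si-ZEB1 replicate 2, 1621 and 1133 without si-WNT5A replicate 1 or 2, and 1410 without the double transfection's replicate 2.

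The DNA replication list had a positive interaction (8 higher and 0 lower of 40, and 16 and 1 adjusted over the list alone; adjusted p = 0.000164, and adjusted p = 0.657 with an estimated correlation), and the p53 list a negative one (0 higher and 8 lower of 25, and 0 and 9 adjusted over the list alone; adjusted p = 0.0017, and adjusted p = 0.626 with an estimated correlation). The miR-200 family targets were positive (2 higher and 0 lower of 30, also adjusted over the list alone; adjusted p = 0.0201, and adjusted p = 0.626 with an estimated correlation). The unfolded protein list was negative (0 higher and 4 lower of 30, and 0 and 5 adjusted over the list alone; adjusted p = 0.0358, and adjusted p = 0.682 with an estimated correlation). The miR-200 target call was lost without si-ZEB1 replicate 1, si-WNT5A replicate 2 or the double transfection's replicate 2 (adjusted p = 0.0814, 0.113 and 0.107). The unfolded protein call was lost without si-NC replicate 2, si-ZEB1 replicate 2, si-WNT5A replicate 1 or the double transfection's replicate 2 (adjusted p = 0.249, 0.0688, 0.343 and 0.187).

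**Figure D4:**
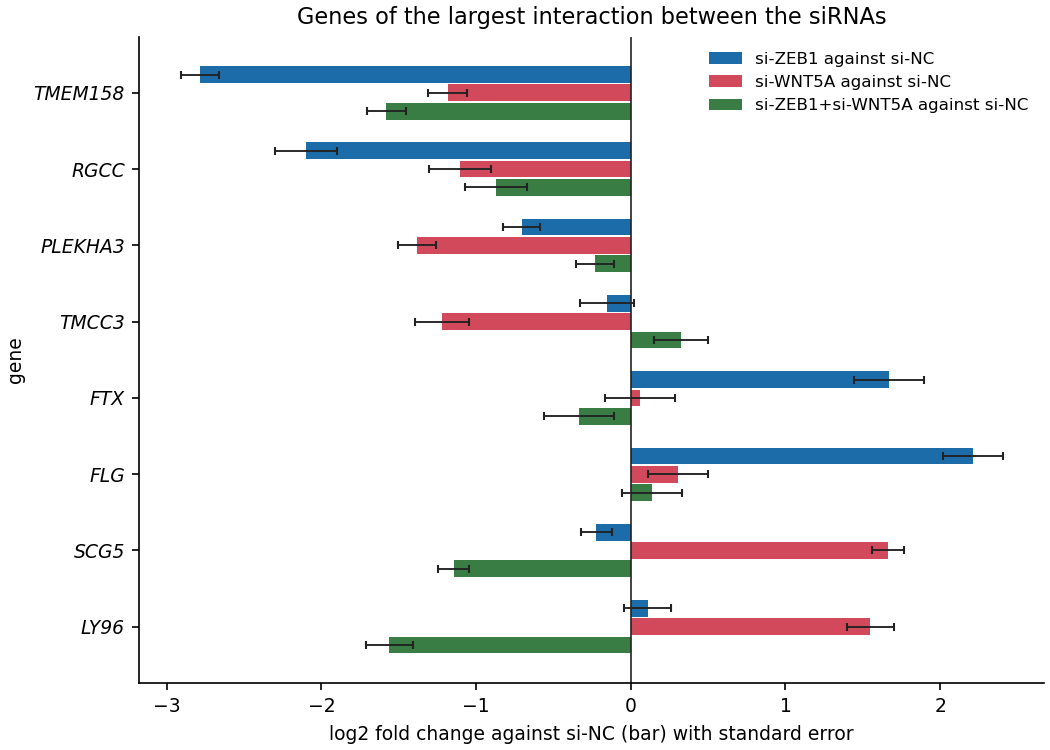
Change from si-NC (log2, horizontal axis) with si-ZEB1, si-WNT5A and both siRNAs for the 8 genes with the highest and lowest interaction, 1 bar a treatment with the SE of the fit. LY96 lies at 1.55 with si-WNT5A and at −1.56 with both, and TMEM158 at −2.79 with si-ZEB1 and −1.58 with both.

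The genes that the siRNAs moved were then followed in the miRNA experiment, which shares no arrays with them. The 623 genes lower with si-WNT5A were lower than other genes with miR-141 (median −0.26, adjusted p = 0.000392) and miR-200b (median −0.21, adjusted p = 0.000416), and adjusted p = 0.97 with an estimated correlation in each case. With miR-141 100 of them were called higher and 145 lower, where independence would give 94.4 and 59.5. With miR-200b the counts were 48 and 83 against 43.4 and 30.3. With miR-205 they were 97 and 97 against 90.6 and 44.9, and the set did not pass (adjusted p = 0.0666). The 3067 genes higher with si-ZEB1 did not pass as a set with miR-141 (adjusted p = 0.223), miR-200b (adjusted p = 0.782) or miR-205 (adjusted p = 0.67). Calls in both directions were more frequent than independence gives. With miR-141 645 were higher and 499 lower against 464.8 and 292.8. The counts with miR-200b were 404 and 222 against 213.6 and 149.4, and with miR-205 735 and 361 against 445.9 and 221. Of 18 such tests 2 passed, against 6, 4 and 1 without miR-141 replicate 1, 2 or 3. With the GAPDH covariate 13 passed, all of them lower, among them the genes lower with si-WNT5A in miR-205 (adjusted p = 4.13e-06). Without the 3 arrays of low 5′ signal the same genes missed the threshold in the 1 miR-141 array left (adjusted p = 0.312).

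Wnt pathway genes did not pass as a list by camera in any comparison. By fry, which does not compare them with other genes, they passed with si-ZEB1 (up, adjusted p = 0.0155), si-WNT5A (down, adjusted p = 0.0194) and both siRNAs (down, adjusted p = 0.0426), and their median and mean differed in sign with si-ZEB1 (−0.02 and 0.06) and si-WNT5A (0.02 and −0.09). The transcription factor LEF1 fell with miR-141 (−2.77 ± 0.36, adjusted p = 0.000495) and miR-205 (−2.98 ± 0.36, adjusted p = 0.000301) and the receptor FZD6 with miR-200b (−2.36 ± 0.42, adjusted p = 0.00442). Of 36 Wnt genes 5 were higher and 9 lower with miR-141 (6 and 9 adjusted over the list alone), 1 and 4 with miR-200b (1 and 6 adjusted over the list alone) and 4 and 6 with miR-205. The counts were 12 and 8 with si-ZEB1, 0 and 5 with si-WNT5A (2 and 6 adjusted over the list alone) and 8 and 8 with both siRNAs. Of 44 interferon response genes 4 were higher and 2 lower with miR-141 (2 and 2 adjusted over the list alone), 1 and 2 with miR-200b, 6 and 2 with miR-205, 9 and 7 with si-ZEB1, 2 and 2 with si-WNT5A and 5 and 7 with both. Small RNA machinery genes, 13 in number, gave 0 and 3, 0 and 1, and 2 and 2 with miR-141, miR-200b and miR-205, and 4 and 1, 0 and 2, and 5 and 1 with si-ZEB1, si-WNT5A and both. None of 13 blood cell markers was called by limma in any comparison with a control, and 4, 1 and 1 had an unadjusted p under 0.05 with miR-141, miR-200b and miR-205 and 2, 3 and 1 with si-ZEB1, si-WNT5A and both. Of 12 endothelial markers 4 were higher and 0 lower with miR-141, 0 and 0 by limma with miR-200b (3 at an unadjusted p under 0.05), 2 and 1 with miR-205, 2 and 3 with si-ZEB1, 0 and 1 with si-WNT5A and 1 and 5 with both. Of 11 reference genes the counts were 0 and 1, 0 and 0 (3 at an unadjusted p under 0.05), and 2 and 1 with miR-141, miR-200b and miR-205, and 2 and 3, 0 and 0 (1 at an unadjusted p under 0.05), and 0 and 3 with si-ZEB1, si-WNT5A and both. No test of these 6 lists passed by camera in either experiment. By fry the blood cell (adjusted p = 0.044) and endothelial markers (adjusted p = 0.0281) passed upwards with miR-141, the interferon list upwards with miR-205 against miR-NC (adjusted p = 0.0165) and miR-200b (adjusted p = 0.0194), and small RNA machinery upwards with si-ZEB1 (adjusted p = 0.024). The endothelial markers passed downwards with both siRNAs (adjusted p = 0.0072), as did the reference genes with si-ZEB1 and with both (adjusted p = 0.00497 each).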

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

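The tests of explanations here were chosen only after the result was seen, except the counts over other splits of the arrays, which were planned.

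The siRNA effects differed by whether the other siRNA was present, by limma's interaction test, in 2452 genes. The highest values were 2.39 for TMEM158, 2.33 for RGCC, 1.86 for PLEKHA3 and 1.7 for TMCC3, and the lowest −3.22 for LY96, −2.59 for SCG5, −2.38 for FLG and −2.06 for FTX.

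The effect of si-WNT5A where si-ZEB1 was present did not follow its effect alone: over the 1322 genes called with si-WNT5A, the change on adding it to si-ZEB1 had a slope of 0.07 (0.031 to 0.109) on the change alone, though over all genes it was no smaller (SD of 0.288 against 0.232). WNT5A kept 0.734 of its fall there, near the slope that proportional responses to a weaker fall would have. The slope argues against these as the whole cause, but other responses stay open. If si-NC arrays standing apart had made the si-WNT5A calls, the si-ZEB1 change of these genes would follow the si-WNT5A change with a slope near 1, and it was 0.253. Other handling of the si-WNT5A, si-ZEB1 or double arrays stays open, since each group has its own 2 arrays, and with miR-200b 17 of the 53 genes at least 2-fold lower with si-WNT5A were lower (2.6 by independence) and 6 of the 40 higher were higher (2.8). A dependence of the WNT5A response on ZEB1 may also explain the pattern and was not tested.

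The 3 miRNAs shared 1471 called genes, and a low 5′ signal of the miR-NC arrays, were it the cause, would leave treated arrays of equally low 5′ signal close to miR-NC. The miR-141 replicates 2 and 3 are such arrays (GAPDH differences of 6.89 and 7.56, with miR-NC at 6.63 to 7.90) and miR-200b replicate 3 comes nearest of the others (5.68), and over the 3051 genes shared without them (miR-141 replicate 1 alone) their median deviation was 0.822, 0.943 and 0.797 of that in the other treated arrays, where the GAPDH difference predicts 0.068, −0.052 and 0.28. This argues against low 5′ GAPDH signal as the whole cause. Single genes and other RNA quality stay open. With the GAPDH covariate 897 of the 1471 calls were kept and the percent higher moved from 58.4 to 48.7. Of 100 splits of the 12 arrays 1, the real one, gave as many shared genes. The highest other gave 1165 with the miR-NC arrays kept together and the treated arrays mixed, and splits with other control arrays gave 0. The splits thus show that the miR-NC arrays stand apart from the treated arrays as a block. They cannot tell whether the miRNAs, handling or chance between cultures set them apart. Other handling of the miR-NC arrays cannot be told apart from an effect common to the miRNAs, because every miR-NC array is a control and the experiments were normalized apart, so the slope of the si-NC minus miR-NC difference in percentile on the treated minus miR-NC difference, 0.438 over shared genes and 0.746 over other genes, does not decide.

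miR-205 and miR-141 differed in 1 called gene. Were spread from miR-141 replicate 3 the whole cause, many calls would appear without it, and 7 genes, set by replicates 1 and 2, argue against this, as miR-205 against miR-200b, without it and 1 more of either group's arrays in turn, gave 309 to 1864. Across genes miR-141 replicate 1 correlated with the miR-205 arrays at r = 0.993 to 0.995, as they did with one another (0.994 to 0.997), and 920 genes were called without it, between miR-205 and the 2 miR-141 arrays of low 5′ signal. That it is a miR-205 array cannot be told apart from a like effect of these miRNAs: in 90.8% of the 76 genes in which it stood apart from miR-205 the mean of the other 2 miR-141 arrays lay on the same side (replicate 2 in 98.7% and replicate 3 in 77.6%), against 59.5% of all genes. However, miR-205 replicate 1 set against the other 2 miR-205 arrays gave 92.6% of 122 genes (63.3% of all), replicate 2 41.7% of 12 (47.9%) and replicate 3 76% of 25 (46.6%).

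For the comparisons of 3 arrays with 3, the 10 splits of the 6 arrays are too few for a share under 0.05. The real split gave 4885, 2340 and 4300 genes for miR-141, miR-200b and miR-205 against miR-NC, and the highest other split 0 in each, so 1 split of 10 reached the real value. For miR-205 against miR-141 and miR-200b the real splits gave 1 and 181 genes and the highest other 0. For miR-200b against miR-141 the real split gave 461, and 2 splits reached it, the other with 785 genes. That split, miR-141 replicate 1 with miR-200b replicates 1 and 2 against the rest, follows the arrays of low 5′ signal. With the GAPDH covariate the real comparison called 54 genes.

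Probe sets without a single gene symbol, which no comparison used, were also called by limma against the controls. There were 1775 with miR-141 (733 higher and 1042 lower), 863 with miR-200b (270 and 593), 1733 with miR-205 (574 and 1159), 2043 with si-ZEB1 (1443 and 600), 133 with si-WNT5A (92 and 41) and 926 with both siRNAs (453 and 473), of 13522 tested.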

How the results depend on the processing

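The GAPDH covariate and the fits without the 3 arrays of low 5′ signal were tests chosen only after the result was seen. So were siRNA sets of at least 2-fold and fits without miR-141 replicate 3 in other comparisons. The cause was not tested for any change given here, except that fewer arrays or a wider shared spread enter some fits. Signal over background limits CDH1, which lay near background in all groups, and the arrays per group limit the rest. The seed-match sets were not run.

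With all 20 arrays in 1 fit the counts were 7501, 4368 and 6507 for miR-141, miR-200b and miR-205 against miR-NC, 2986 for miR-200b against miR-141, 110 and 1388 for miR-205 against miR-141 and miR-200b, 2741 shared, 727, 3 and 307 for si-ZEB1, si-WNT5A and both, and 2 for the interaction, as the larger spread of the miRNA arrays enters the siRNA tests. With only the arrays compared, miR-141 gave 1994, miR-205 8523, miR-200b against miR-141 and miR-205 against miR-141 0 each by limma, and miR-205 against miR-200b 558. Array weights, whose fit to the miRNA arrays stopped before convergence, gave 8483 for miR-200b, 9210 for miR-205, 1541 for miR-200b against miR-141, 7 and 8330 for miR-205 against miR-141 and miR-200b, and 3075 shared. The GAPDH covariate gave 7466 for miR-141, 54 for miR-200b against miR-141, and 0 and 510 for miR-205 against miR-141 and miR-200b. Without the 3 arrays of low 5′ signal miR-200b gave 5282, miR-205 8735, miR-200b against miR-141 61, miR-205 against miR-141 0 and against miR-200b 2000, and 3051 were shared.

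For miR-200b against miR-141 a replicate block gave 238, the mean of probe sets 131, dim genes left out 808 and centring 244. For miR-205 against miR-200b the block gave 72, the mean of probe sets 100 and dim genes left out 326. For miR-205 against miR-141 the mean of probe sets and dim genes left out gave 2 each and quantile normalization 4. For si-WNT5A an intensity trend gave 2289 and dim genes left out 1993, and the trend gave 3824 for the interaction. The percent of called genes that were higher moved from 61.4 to 49.5 for miR-141 and from 28 to 43.4 for miR-200b against miR-141 with centring, from 64.6 to 49.4 for miR-205 against miR-200b with quantile normalization, and with the GAPDH covariate from 66.9 to 51.9 for miR-205. With that covariate 4770 of 4885, 1335 of 2340 and 1972 of 4300 calls were kept for miR-141, miR-200b and miR-205. Residuals of arrays with the same number correlated between −0.29 and 0.476 over 18 pairs of arrays in the miRNA experiment, so the numbers were not used as pairs.

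Leaving out 1 array gave 2688 to 5946 for miR-141, 920 to 4634 for miR-200b, 2116 to 6975 for miR-205, 26 to 2549 for miR-200b against miR-141, 0 to 920 and 18 to 1403 for miR-205 against miR-141 and miR-200b, 598 to 2752 shared, 4430 to 5595 for si-ZEB1, 343 to 663 for si-WNT5A, 3328 to 4351 for both, 880 to 2158 for the interaction and 1 to 6 siRNA sets. A lone array is assumed to vary like the other groups, in these siRNA fits and for miR-141 replicate 1 without the 3 arrays of low 5′ signal.

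List tests that passed numbered 28 and 19, 0 and 0 with an estimated correlation, and 18 and 35 with fry. Of the 28, 23 were kept with the GAPDH covariate and 18 without the 3 arrays. siRNA sets that passed numbered 2, and 0 with an estimated correlation, 0 with fry, 5 over the mean of probe sets, 13 with the GAPDH covariate, 1 without the 3 arrays and 5 with sets of at least 2-fold. Directions reversed for the interferon list in miR-205 with fry (adjusted p = 0.0165). In miR-205 against miR-141 the mitosis list reversed with the GAPDH covariate (0.000344), without the 3 arrays (8.25e-09, with 1 miR-141 array) and without miR-141 replicate 3 (0.000636, where leaving out other arrays gave up to 0.985), as did DNA replication without the 3 arrays (0.0113). With the covariate so did genes higher with si-ZEB1 in miR-200b and miR-205 (0.0217 each), genes higher with both siRNAs in miR-205 (0.00775) and CIMIP2A in miR-205 (−0.18). WNT5A reversed in si-ZEB1 at its other probe set (−0.32) and ZEB2 with both siRNAs over the mean of probe sets (−0.33).

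Of 254 values of named genes, 250 kept direction and side of the threshold with centring, 251 with quantile normalization, 250 with the block, 221 over the mean of probe sets and 201 with all arrays in 1 fit. With the GAPDH covariate 119 of 140 did, and leaving out 1 array 1237 of 1328. Of 225 called values, 26 were lost in at least 1 such fit.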

Other observations

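The genes in this part were chosen after their values were seen, as were the tests.

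Genes that moved at least 2-fold with an siRNA were looked up among the miRNA calls. The genes higher with si-ZEB1 that also rose with miR-200b numbered 61, where independence gives 28.3. Among them were ZNF165 (3.12 with miR-200b and 3.41 with si-ZEB1), SPINT2 (2.40 and 2.91), ZBED2 (4.33 and 2.90), the lysosomal channel MCOLN3 (2.31 and 2.86) and CDS1 (3.02 and 2.36). The genes lower in both numbered 78 against 25.6, with SYTL2 (−2.14 and −2.89), TMEM158 (−2.22 and −2.79) and the stem cell receptor LGR5 (−2.08 and −1.87). Opposite calls were also more frequent than independence gives, with 45 genes against 19.8 higher with si-ZEB1 and lower with miR-200b and 41 against 36.6 the other way. With miR-141 the genes moving alike numbered 86 against 61.5 and 94 against 50.2, and with miR-205 90 against 59 and 72 against 37.9. Opposite calls with miR-141 numbered 83 against 38.8 and 103 against 79.7, and with miR-205 58 against 29.3 and 98 against 76.5.

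Genes at least 2-fold lower with si-WNT5A were also lower with miR-141 (15 against 5.1), miR-200b (17 against 2.6) and miR-205 (13 against 3.8). Opposite calls of these genes numbered 6 against 8, 3 against 3.7 and 7 against 7.7. The genes higher with si-WNT5A were higher with miR-141 (7 against 6.1), miR-200b (6 against 2.8) and miR-205 (7 against 5.8), and lower in 7 against 3.8, 5 against 1.9 and 4 against 2.9. Among the genes lower in both were SEMA3C (−2.98 with miR-141, −3.60 with miR-200b and −1.74 with si-WNT5A) and MAMDC2 (−2.63, −2.90 and −1.56). The metalloprotease inhibitor TIMP3 (−2.31 with miR-141 and −1.31 with si-WNT5A) and osteopontin, SPP1 (−3.11 and −1.22), fell in both as well.

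The other siRNA order gave a larger slope. Over the 6445 genes called with si-ZEB1, the change on adding si-ZEB1 to si-WNT5A had a slope of 0.595 on the change with si-ZEB1 alone, with 82.6% of genes of the same sign, while ZEB1 itself kept 0.87 of its fall.

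By the gap between their nearest arrays, the BMP antagonist GREM1 lay furthest apart between miR-141 and miR-205 (gap of 1.62), without passing (adjusted p = 0.245 by limma). Its means were 5.02 ± 1.47 against 7.68 ± 0.10 (SD, n = 3 each). The complement binder C4BPB (4.73 against 6.84) was higher with miR-205 and ANGPTL4 (7.31 against 5.25) with miR-141, also without passing.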
